A study of Mus musculus with 4 samples.

How the data were processed

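Chromatin of AGM cells was crosslinked in 0.5% formaldehyde and sheared to about 1000 bp, per the labels' protocols. DNA precipitated with an anti-RBPj antibody, per the antibody label, was labelled with 1 dye and input DNA with the other. The sample titles say RBP2 ChIP, and the antibody label and the series title were followed here. The arrays tile promoters from -5.5 kb to 2.5 kb around annotated starts with about 25 probes per gene and about 200 bp between probes, per the series text. Replicates 1 and 2 are slide design 1 and replicates 3 and 4 are slide design 2. Replicates 1 and 3 carry the ChIP in Cy5 and replicates 2 and 4 in Cy3, per the labels. The slide designs hold different promoters, so they were scored separately.

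The scanner files hold 1 array each. Spots were measured with Agilent Feature Extraction 9.5.1.1, per the file headers, while the submitters' processing notes name version 8.5.1.1. Spot and background intensities were deposited as raw pixel brightness and, per the file headers, as processed signals after background subtraction, multiplicative detrending and linear dye normalisation. In a check on the files, 100.0% of processed signals equalled the detrended signal times 1 factor per channel, within 0.001 of that factor. The check covered gene probes for which the scanner software flagged no substitute value in either channel. The log10 ratio of Cy5 over Cy3 processed signal was deposited for each spot, as the column names per the file headers give it. A p-value from the scanner software's error model was also deposited for each spot, and it was used only to describe arrays: 14.4% to 20.1% of probes had a value under 0.01. The log2 table deposited with the series matched the log2 ratio of ChIP over input of background-subtracted median signals within 0.001 for 98.8% to 99.99% of probes. Its values are not centred, with medians of 0.36, -0.37, 0.47 and -0.54 for replicates 1 to 4, and it was used as an alternative. The steps by which the authors made it and the genome build of the probe positions were not given in the sources used here.

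The log10 ratios were turned into log2 ChIP over input by the dyes in the labels and centred on each array's median, with no loess or quantile step. Control spots and 15 to 46 outlier-flagged probes per array were left out, and saturated probes (2 on replicate 3, 0 elsewhere) were kept. The window score of a probe was the mean over all probes within 500 bp on each side, averaged over both arrays, where at least 3 probes were measured. This gave 430074 windows, with a median of 5 probes each. Scores were turned into robust z values with the median and 1.4826 times the median absolute deviation of each slide design. A region was a run of windows with a z of at least 4, each also above the 95th percentile of windows on both single arrays, and runs at most 1000 bp apart were joined. The threshold was a log2 ratio of 1.24 on slide design 1 and 1.18 on slide design 2. The design has 1 precipitate, so this is a rule of size without a test across samples.

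Genes and distances to starts come from the array annotation. Symbols were updated through RefSeq accessions with a gene table of the GRCm38.p6 assembly, which matched 16943 of 17596 annotations. The remaining names are those of the array. No coordinates of that assembly were used. A gene's score was its highest window. There were 18 gene lists, and for each the median score was set against 10000 random lists of equal size, matched on deciles of probe number and input intensity, as a description of these arrays. The lists, the rule and the alternatives were fixed before the data were examined, apart from the alternatives that the closing section names as chosen later. Named genes were all measured known Notch targets, summarised beyond the called ones, the 15 called genes with the highest scores, the 5 genes with the lowest window, up to 4 called members of each other list, and Cdca7, Runx1, Gata2, Hes1, Hey1, Hey2, Heyl, Nrarp, Gfi1, Dll4, Jag1 and Efnb2. Intervals of shares are exact binomial intervals.

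The rule was tested on simulated ratios on the 473642 real probe positions, with a correlated background of the measured spread and 200 planted peaks. It found 8.0% of peaks of height 1 on the log2 scale, 48.0% of height 1.5, 94.0% of height 2 and 100.0% of height 3. Height was that of the apex, from which a peak fell off linearly over 1000 bp on each side. The mean window ratios at these peaks were 0.68, 1.22, 1.59 and 2.39. A simulated list of 25 genes raised by 1 SD lay at the 100.0th percentile and an unraised list at the 72.4th, over 16558 genes. Alternatives changed the background correction (limma normexp, offset 50), the normalisation (loess, span 0.3), the source of the ratios, the dim probe filter, the standardisation, the window, the threshold, the single-array requirement and the arrays used. Motif content and probe GC content were not analysed here, since no sequence was used. Computations used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.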

Results

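RBPj, the DNA-binding protein through which activated Notch receptors act on their target genes, was precipitated with its chromatin from the aorta-gonad-mesonephros (AGM) of CD1 mouse embryos at E11.5. The AGM is the embryonic region around the dorsal aorta in which haematopoietic stem cells arise. Chromatin came from a pool of 40 dissected AGMs, and the precipitated DNA was hybridised against sheared input DNA on promoter arrays. The promoter set filled 2 slide designs, and each was hybridised on 2 arrays with the dyes exchanged, which gave 4 arrays. Both arrays of a slide design carried the same precipitate and input, so they count as 1 replicate. Each ± below is therefore the SD of 2 technical measurements, and no p-value was computed. A control-antibody hybridisation mentioned with the series was not analysed here. The arrays held 474380 gene probes in all, of which 473642 had a genome position. Median spot brightness was 3.29 to 5.31 times the local background, and between 99.7% and 99.8% of probes on each array were well above background in both channels. The number of arrays limits the precision.

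The first comparison asked which promoters carried more DNA in the RBPj precipitate than in the input. The highest ratio lay at Rpl32, a gene for a protein of the large ribosomal subunit, with a window log2 ratio of 2.57 ± 0.06 (SD, n = 2 arrays) or 5.93-fold. Hes1, a transcriptional repressor and textbook Notch target, came next with 2.14 ± 0.06, or 4.40-fold, followed by Arid5b, a gene for an ARID-domain DNA-binding protein, with 2.12 ± 0.05. The windows of Rpl32 and Hes1 held 3 probes, the fewest allowed, and that of Arid5b held 6. Cdca7, a gene tied to cell division, reached 2.00 ± 0.07, or 3.99-fold. Axin2, a negative regulator of Wnt signalling, reached 1.93 ± 0.16, or 3.82-fold.

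In all, 68 regions at 71 genes were called, which is 0.429% of the 16558 genes with a score. Their highest windows ranged from 2.28-fold to 5.93-fold, with a median of 2.47-fold, and the median SD of the 2 arrays was 0.065 on the log2 scale. The other high genes by the naming rule covered several cell functions. Riok2, a kinase of ribosome maturation, had a log2 ratio of 2.04 ± 0.03, and Ostc, a part of the oligosaccharyltransferase complex, had 2.04 ± 0.03. Wasf1, an actin regulator of the WAVE family, had 2.03 ± 0.05. Camkmt and Prepl shared 1 region, where the window nearest Camkmt reached 2.06 ± 0.05. Taf6, which encodes a subunit of the general transcription factor TFIID, shared a divergent promoter with Cnpy4, and their window reached 1.96 ± 0.07. Dhx35, a DEAH-box helicase gene, had 1.84 ± 0.09, and the linker histone gene H1f2 had 1.61 ± 0.13. H2bu2, a histone H2B gene, had 1.99 ± 0.42, the largest SD among called regions, and its highest window lay at -9421 bp from the annotated start, negative values being upstream.

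Positions are those in the array files, whose genome build was not given in the sources used here. The Hes1 region ran from 29984625 to 29986309 on chromosome 16. Its highest window was centred on a probe 83 bp downstream of the start, while its strongest single probes lay at 550 and 841 bp. The Cdca7 region ran from 72276384 to 72277334 on chromosome 2. Its highest window was equal for the probes at -497 and -338 bp, and its strongest single probe lay at -185 bp. The Axin2 region ran from 108736522 to 108737289 on chromosome 11, and the Rpl32 region from 115774044 to 115774875 on chromosome 6. The array annotation placed 41 regions in a promoter, 3 in a divergent promoter, 23 inside the transcribed unit and 1 away from any RefSeq gene.

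**Figure D1:**
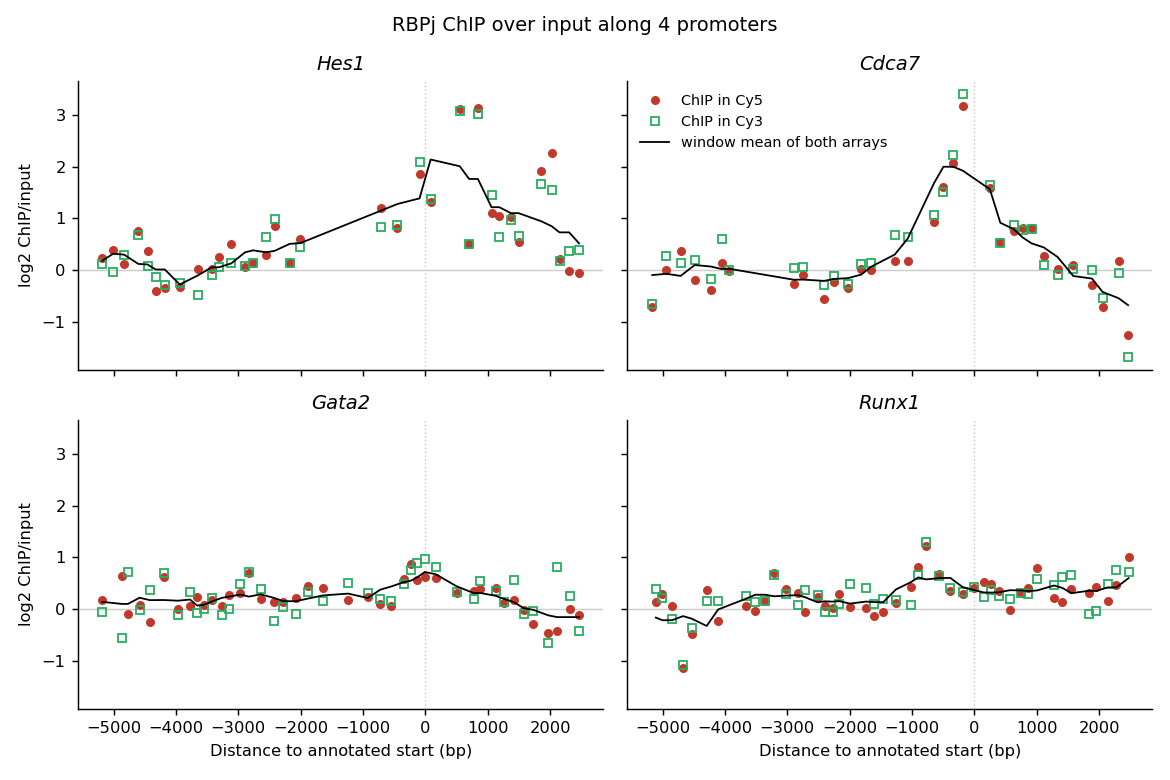
Log2 ChIP/input ratios along the promoters of Hes1, Cdca7, Gata2 and Runx1, by distance to the annotated start in bp; each symbol is 1 probe on 1 array (filled red, ChIP in Cy5; open green, ChIP in Cy3) and the black line is the mean of both arrays over probes within 500 bp. The line peaks at 2.14 for Hes1 and 2.00 for Cdca7, and stays at or below 0.72 for Gata2 and 0.61 for Runx1.

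The number of calls depended on the rule. It ran from 19 regions at a robust z of 5 to 977 at a robust z of 3. In ratios simulated with the measured spread the main rule called 40 regions that held no planted peak, against 0 at a z of 5. That spread includes any real enrichment, so the 40 does not estimate the false calls among the 68 regions. At the main threshold, the difference between arrays divided by 2 gave 0 regions on either side, which covers technical noise only. Hes1, Cdca7, Axin2, Rpl32, Arid5b, Riok2, Ostc, Wasf1, Taf6, Dhx35, H1f2, H2bu2, Camkmt, Prepl, Elmod2 and Uqcrc2 were called under each of the 19 settings tried, the main one included. Some settings could not lose a main call, such as a z of 3 or a 2-fold threshold.

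A second question was whether genes known to respond to Notch stood out. Of 25 measured genes on the list of known Notch targets, Hes1 was called. Without replicate 1 the count was 2, and under normexp it was 4, where calls over all genes rose from 71 to 391. Hey1 (1.18 ± 0.30), Hey2 (1.08 ± 0.10) and Nrarp (1.08 ± 0.02), which encode 2 transcriptional repressors and a feedback inhibitor of Notch signalling, lay above 2-fold but under the threshold, with robust z values of 3.81, 3.66 and 3.49. Hes7 (0.94 ± 0.08) and Hes5 (0.94 ± 0.23) reached z values of 3.17 and 3.04. With Hes1, 6 of the 25 genes (24.0%, exact 95% interval 9.36% to 45.1%, covering counting error only) had a z of at least 3, against 6.64% of all genes. The share of all genes was not matched on probe number. Such a share was not particular to this list. It was 22.6% for histone genes, 21.7% for Notch pathway components and 41.7% for the Hes and Hey family, and at most 13.9% for the other lists. The median gene score of the known Notch targets, the highest window of each gene in robust z units, was 2.28 and lay at the 99.4th percentile of 10000 matched random lists. After the mean of the probes 1500 to 4000 bp away was removed, a step chosen after seeing the data, that percentile was 67.1.

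The remaining targets had lower windows, the highest at Ccnd1 (0.903 ± 0.232) and Igf1r (0.903 ± 0.225), each with a z of 2.91. Runx1 and Gfi1 below are not on the list and were named by the rule. Gata2, a regulator of haematopoietic stem cell formation, had a log2 ratio of 0.72 ± 0.10, and Runx1, required for blood formation from endothelium, had 0.61 ± 0.05. Heyl had 0.71 ± 0.01, the Notch ligand gene Jag1 had 0.70 ± 0.17, and the ligand gene Dll4 had 0.31 ± 0.11. The arterial gene Efnb2 had 0.37 ± 0.12 and the repressor gene Gfi1 had 0.43 ± 0.08. Il2ra was the lowest of the list with 0.22 ± 0.07.

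Among 46 Notch pathway components, Rbpj itself was called, with a log2 ratio of 1.39 ± 0.06 or 2.62-fold in a window at -65 bp from its start. Rbpj was not called at a robust z of 5, nor after removal of the flanking mean or of the average profile around starts. Its flanking mean was -0.054, and its window exceeded that mean by 1.443 on the log2 scale. The call lost with the flanking mean therefore does not show a ratio raised over the whole Rbpj promoter. Under normexp 5 components were called, and 7 with a 2-fold threshold. In that list 10 genes (21.7%) had a z of at least 3. Its median score lay at the 68.2nd percentile of matched random lists, between 55.6 and 89.5 with single arrays left out, at 99.92 by the mean ratio over all probes and at 99.37 after the start profile was removed. The Hes and Hey family, which overlaps the target list, had Hes1 called among 12 genes, with 2 genes called without replicate 1 and 3 under normexp, and lay at the 97.4th percentile, at 95.4 under normexp and at 81.9 without the flanking mean. Of 42 haematopoietic stem and progenitor genes, Cdca7 was called. That list lay at the 34.6th percentile, at 2.07 without the flanking mean, at 67.2 by the mean ratio over all probes and at 83.1 without the start profile. Cdca7 was also the called gene among 37 cell cycle genes, while 2 were called without replicate 3 and 3 under normexp. They lay at the 97.7th percentile, at 95.9 without replicate 1 and at 95.1 without the flanking mean. The study singled out Cdca7 on these arrays, so its place in both lists is not independent evidence.

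Cell type and pathway lists differed in their median score, and for several of them the position depended on how a gene was scored. Among 36 genes of the Wnt, BMP and hedgehog pathways, Axin2 was called (2 genes under normexp) and the list lay at the 99.6th percentile, or 54.5 without the flanking mean. None of 24 arterial endothelial genes was called, but 3 were under normexp and 1 without replicate 1. The list lay at the 90.6th percentile, between 74.1 and 93.1 with single arrays left out, at 99.95 by the mean ratio over all probes and at 58.2 without the flanking mean. None of 23 venous and general endothelial genes was called. They lay at the 0.70th percentile, but at 85.7 by the mean ratio, at 68.8 without the start profile and at up to 2.60 with single arrays left out. The 21 erythroid and myeloid genes had no call and lay at the 0.01th percentile, or 2.53 without the start profile. The 28 urogenital ridge and mesonephros genes had no call and lay at the 1.14th percentile, between 0.57 and 4.04 with single arrays left out, at 76.3 by the mean ratio and at 31.7 without the start profile. The 17 sympathoadrenal and neural crest genes had no call and lay at the 1.61st percentile, at up to 5.63 with single arrays left out, at 78.2 by the mean ratio and at 65.9 without the start profile. The 22 mesenchyme and smooth muscle genes had no call and lay at the 39.9th percentile, at 99.5 by the mean ratio, at 1.38 without the flanking mean and at 10.7 without replicate 4. The 33 Hox genes had no call and lay at the 12.8th percentile, at 100.0 by the mean ratio, at 96.3 without the start profile, at 0.09 without the flanking mean and at 5.92 without replicate 3. Among 22 housekeeping genes none was called, but 2 were under normexp. The list lay at the 93.8th percentile, at 99.48 by the mean ratio and at 97.485 without replicate 3. None of 35 genes restricted to other tissues was called, and no random list had a median as low as theirs.

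Histone, ribosomal protein and olfactory receptor genes also lay outside the central 95% of matched random lists. Of 53 histone genes, H2bu2, H1f2 and H1f3 were called (8 genes under normexp), and 12 had a z of at least 3. The median histone score was 2.16, at the 99.99th percentile, or 54.2 without the flanking mean. H1f3, a linker histone gene, had a log2 ratio of 1.24 ± 0.02. Of 86 ribosomal protein genes, Rpl32 was called (5 genes under normexp, 3 under loess and 2 without replicate 3) and 10 had a z of at least 3, with a median score of 2.26 at the 99.99th percentile. None of 826 olfactory receptor genes was called, though 1 was under loess and 1 without replicate 1, and their median score of 0.17 lay below that of every random list. The median log2 ratio within 500 bp of the start was 0.58 for ribosomal protein genes, 0.55 for histone genes and -0.23 for olfactory receptor genes, against 0.41 for all genes. The signs of these medians were the same under normexp, loess and the deposited value table, but the olfactory receptor median was -0.135 under normexp and -0.110 under loess.

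**Figure D2:**
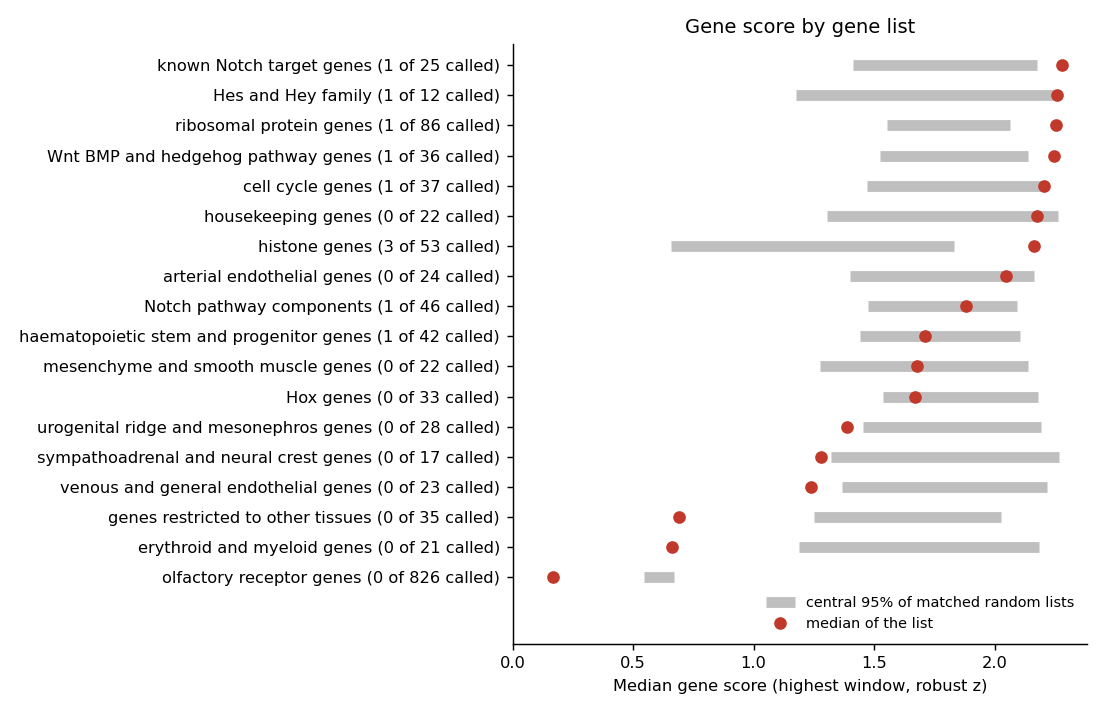
Median gene score of each of 18 gene lists (red points, robust z of the highest window per gene on the horizontal axis) beside the central 95% of 10000 random lists matched on probe number and input intensity (grey bars). Known Notch targets have a median of 2.28 and olfactory receptor genes 0.17.

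A further comparison set the called regions against their distance from the annotated start. Of 67 called regions with a gene, 48 (71.6%, exact 95% interval 59.3% to 82.0%) had their highest window centred within 500 bp of a start, where 17.9% of all windows lay. Within 1000 bp the count was 64 of 67 regions (95.5%, interval 87.5% to 99.1%), against 33.0% of windows. Marcks, Tac4 and H2bu2, named here after their values were seen, peaked further away. Probes of all genes also had higher ratios near starts, with a mean log2 ratio of 0.41 between 0 and 250 bp downstream and -0.11 from -5000 to -4750 bp. Called genes, which were chosen for high windows, reached 1.38 ± 0.08 (SE over 94 probes) from -250 to 0 bp, and ribosomal protein genes reached 0.73 ± 0.04 (SE over 119 probes). After the average profile around starts was removed, a step chosen after seeing the data, 52.5% of called regions lay within 1000 bp.

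**Figure D3:**
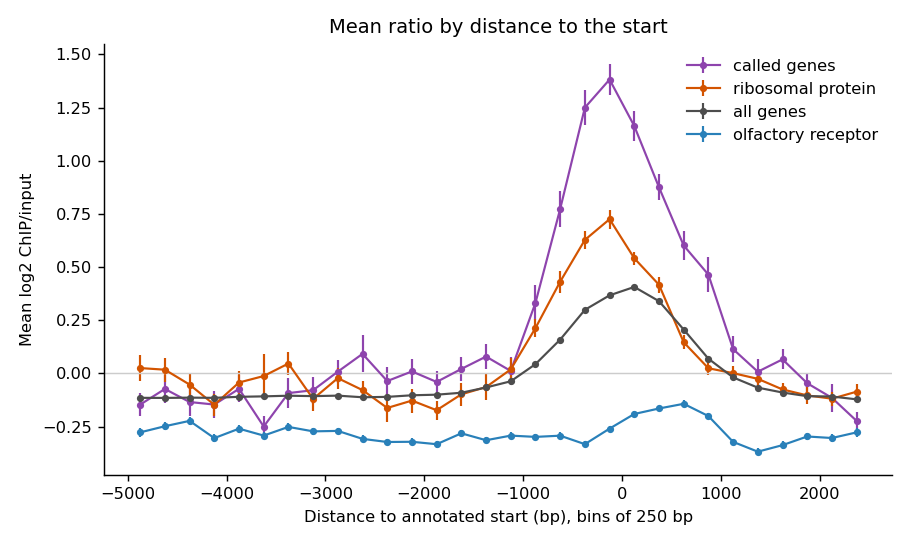
Mean log2 ChIP/input ratio in 250 bp bins of distance to the annotated start (bp) for called, ribosomal protein, all and olfactory receptor genes; error bars are SEs over probes and do not measure replicate error. Called genes peak at 1.38 and all genes at 0.41, while olfactory receptor genes stay below 0.

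The same rule on the negative side called 28 regions. The count was 55 without replicate 2, 47 without replicate 4, 4 under normexp, 16 under loess, 18 without the flanking mean and 167 without the start profile. Olfactory receptor genes made up 9 of the 27 depleted regions with a gene (33.3%, exact 95% interval 16.5% to 54.0%), although they were 4.99% of measured genes. The lowest windows were at Olfr24 (-1.70 ± 0.01), the transketolase-like gene Tktl1 (-1.56 ± 0.22) and Rapgef6 (-1.49 ± 0.30). Robo2, an axon guidance receptor gene, had -1.45 ± 0.09, and Olfr963 had -1.42 ± 0.46. Under normexp these windows were nearer to 0, with -0.69 for Olfr24, -0.29 for Tktl1, -0.24 for Rapgef6, -0.34 for Robo2 and -0.28 for Olfr963. With a window of 1000 bp, Olfr24 had -0.67, Rapgef6 -0.72, Robo2 -0.80 and Olfr963 -0.79, and in the deposited value table Rapgef6 had -0.42. Enriched regions were 70.8% of enriched and depleted regions together, a share that ran from 29.5% without the start profile to 98.9% under normexp and was 50.5% without replicate 2.

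The dye-swapped arrays were then compared over all probes. The orientation-corrected log2 ratios correlated with a Pearson r of 0.816 on slide design 1 and 0.818 on slide design 2, with Spearman values of 0.813 and 0.794. Window means correlated with an r of 0.924 and 0.925. These correlations run across probes, which are not independent replicates. The robust SD of the window means was 0.31 and 0.30 on the log2 scale, and that of the difference between arrays, divided by 2, was 0.06 on both designs.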

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

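The alternatives that removed the flanking mean (probes 1500 to 4000 bp away), removed the average profile around starts, or required at least 2 consecutive windows were chosen after seeing the data. The main rule called 68 regions and 71 genes. Normexp called 361 regions and 391 genes, loess 131 and 138, a window of 1000 bp 28 and 29, a z of 3 977 and 1099, a z of 5 19 and 22, a 2-fold threshold 479 and 533, and at least 2 consecutive windows 38 and 42; the cause was not tested, except that thresholds change counts by construction. The other alternatives stayed within 1.5 times the main counts, but shared genes fell to 46 of 71 with a 300 bp window, 34 without the flanking mean and 36 without the start profile. With single arrays left out, calls ran from 56 to 77 regions and 59 to 81 genes. Hes1 was called in every setting. Known Notch targets called numbered 1 in the main setting, 4 under normexp and the 2-fold threshold, 6 at a z of 3, 2 without the start profile, and 1 to 2 with single arrays left out, where Hey1 joined without replicate 1. The percentile of that list was 99.42, and became 100.0 with the mean ratio over all probes, 99.57 when matched on probe number only, 99.1 under normexp, 99.98 without the start profile, 67.1 without the flanking mean, and 99.24 to 99.84 with single arrays left out. The share of regions within 1000 bp of a start was 95.5%, and 52.5% without the start profile. The dye swap correlation of 0.816 and 0.818 became 0.760 and 0.679 under normexp, 0.789 and 0.783 under loess, and 0.821 and 0.822 for probes well above background. The count of depleted regions went from 28 to 332 at a z of 3, 2 at a z of 5, 184 with a 2-fold threshold and 12 with at least 2 consecutive windows. The share of enriched regions was 89.1% under loess, 58.3% with a 1000 bp window and 57.7% without replicate 4. In settings that could move them, window ratios of named genes stayed within their SD in 162 of 371 comparisons. These include 46 of 46 for probes well above background, where the largest shift was 0.000. The counts were 14 of 48 genes under normexp, 11 of 48 under loess, 36 of 48 in the deposited value table and 18 of 37 with a 300 bp window. With a 1000 bp window 5 of 48 stayed, and the median shift was 0.424. The 240 comparisons that left out an array or pooled the standardisation stay within it by construction. Rapgef6 and Olfr963 had no value at their lowest window when probes had to be well above background. No called value changed sign, but 1 uncalled named window ratio did with a 1000 bp window and 1 without the start profile. Motif and GC alternatives were not run, since no sequence was used. Median signal over background of 3.29 to 5.31 limits how low a ratio can be measured.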

Other observations

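Further called genes, chosen after their values were seen, included regulators of chromatin and transcription. Kdm5c, a histone H3 lysine demethylase gene on the X chromosome, had a window log2 ratio of 1.47 ± 0.02. The acetyltransferase gene Kat5 (1.19 ± 0.05) and its partner in the same complex, Ep400 (1.26 ± 0.13), were both called. Hinfp, which encodes a regulator of histone gene transcription, had 1.23 ± 0.03. Kat5, Ep400 and Hinfp each rested on 1 passing window, with robust z values of 4.03, 4.06 and 4.17. At a z of 4 the simulation called 40 regions that held no planted peak, against 0 at a z of 5. Its background had the spread of all measured ratios, so this does not estimate how many such calls are false. Genes of mitochondrial function were also called, among them Uqcrc2, a subunit of respiratory complex III, with 1.59 ± 0.06, and Timm44, a part of the protein import machinery, with 1.57 ± 0.03. No enrichment of these groups was tested. Kat5 was called in 10 of 19 settings, Ep400 and Hinfp in 13, Kdm5c and Timm44 in 17, and Uqcrc2 in 19. These counts include settings that could not lose a main call. They are the main rule, a z of 3, a 2-fold threshold, no single-array requirement, and leaving out an array of the other slide design.

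The 47 mitochondrial genome probes had a median log2 ratio of -0.81, with -0.89 on the arrays with ChIP in Cy5 and -0.76 on those with ChIP in Cy3. Chromosome medians of the autosomes lay between -0.04 and 0.03. The X chromosome median was -0.04 over 17339 probes, and that of the Y chromosome -0.12 over 204 probes.

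Of the tests below, the removals of the flanking mean and of the start profile, the shares left under normexp and loess, the class difference away from every start, and the joining of regions over both arrays were chosen after the data were seen, and the design has a single group, so no biological explanation was tested. The called regions formed peaks. With the highest probe taken out, 100.0% of the 68 regions (exact 95% interval 94.7% to 100.0%) kept a mean of their other window probes above the 95th percentile of windows. The rule already required a high mean over at least 3 probes, so in windows of many probes this outcome was nearly fixed. It was freer to fail in the 16 regions whose highest window held 3 probes, and for those it argues against single bright probes. The highest windows exceeded the probes 1500 to 4000 bp away by a median of 1.475 on the log2 scale (bootstrap interval 1.42 to 1.55, 66 regions). The rule chose windows for their height, so a part of this excess was fixed in advance. The flanking probes were not chosen, and an offset of the whole promoter would have raised them with the window. The excess therefore argues only against an offset that alone accounts for the window ratios. A smaller offset beneath a peak stays open. Of 100 distinct regions called from the ratios of a single array, 37 of them on both arrays in turn, 98.0% (93.0% to 99.8%) lay above the 95th percentile on the array of opposite dye, which argues against dye bias. Antibody background and GC content stay open, since neither a control antibody nor sequence was analysed here.

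Ribosomal protein and olfactory receptor genes sat apart in their mean ratio over all probes, by 0.39 on the log2 scale. After a smooth trend on input intensity was removed, 67.1% of this difference was left (bootstrap interval 64.2% to 73.9%), which lies between the bounds of 50% and 80% set in advance. Loess, which removes a trend on the mean brightness of both channels, left 42.1% (38.1% to 48.7%), and normexp left 58.3% (53.9% to 62.2%), so brightness may carry a part whose size depends on the correction. Over probes more than 2000 bp from every annotated start the classes still differed by 0.206 (bootstrap interval 0.183 to 0.238), which argues against a difference at starts alone in the main ratios. This value was not recomputed after loess, normexp or removal of the input trend, so brightness may carry a part of it. Probes more than 2000 bp from a gene's own start showed 27.6% (23.9% to 35.4%) of the difference seen within 500 bp. This interval spans the bound of 25% set in advance, so that bound was not decided. Even its lower end leaves a part of the difference away from the start, in ratios without a brightness correction.

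The known Notch targets sat at the 99.4th percentile of matched lists. With the average profile around starts removed they lay at the 99.98th percentile, but matched lists share such an offset, and the same step carried 5 of 9 other lists from below the middle of the random lists to above it, so this bound decides nothing and the explanation stays open. With each promoter's own flanking mean removed they lay at the 67.1st percentile, so a ratio raised over the whole promoter, in place of a peak, is a candidate explanation for the position of the list. Hes1 was called after both steps. Under the same removal the ribosomal protein genes lay at the 99.83rd percentile and the histone genes at the 54.2nd.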
